A study of Mus musculus with 31 samples.

How the data were processed

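RNA of iPSCs and of embryoid bodies grown from them was measured on 31 Affymetrix arrays, 1 per sample. Per the labels' protocols, the cells were reprogrammed with Sendai virus from tail-tip fibroblasts of adult male mice, kept at day 0 on growth-arrested mouse embryonic fibroblasts, and aggregated in microwells for spontaneous differentiation until day 11, and biotinylated cRNA was hybridized. The authors summarized the arrays with RMA, per the submitters' processing notes, which give no software version and no further filter or batch step. The deposited values are log2 intensities, which was checked on the values: they run from 2.32 to 15.01, with medians within 0.10 of each other, up to 6.23, on the 31 arrays. The table holds 45101 probe sets and 0 missing values, 0 pairs of arrays were identical, and the highest correlation between 2 arrays was 0.997. No batch or scan date is given.

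Gene symbols came from the platform table supplied with the series. Of the probe sets, 34958 carry 1 symbol, 932 several and 9211 none, and 34754 of those with 1 symbol matched a mouse gene table of assembly GRCm38.p6. Each gene was represented by its probe set with the highest mean over all arrays, which left 18194 genes, 9012 of them with more than 1 probe set. Log2 values as deposited were fitted with limma 3.58.1 in R 4.3.3, with a mean per group (control day 0, n = 10; Nos3-/- day 0, n = 6; control day 11, n = 9; Nos3-/- day 11, n = 6) and an empirical Bayes variance, with 27 residual and 2.80 prior degrees of freedom. The 5 comparisons were Nos3-/- minus control on each day, day 11 minus day 0 in each genotype, and the difference between genotypes in that change. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and the genes changed by 1 or more on the log2 scale are counted beside this. Standard errors are those of the moderated fit, and ± gives the SD between arrays.

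Gene lists for cell types and germ layers, the heart, signalling pathways, metabolism and stress, and checks of feeder cells, strain and sex were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the first set of alternatives. Of 1077 entries in 42 lists, 1001 were measured, and 41 lists had at least 5 genes and were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. In the 81 list calls, the median, the mean and the test had 1 sign, and in 22 of the 124 results not called they differed. Members are counted as passing over all genes and, separately, adjusted over the list alone.

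By the naming rule, the text may give Nos3, the 8 highest and 8 lowest genes of each comparison of 2 groups among those passing without overlap between the groups (6 and 6, without the condition on overlap, for the difference between genotypes over time), and from each list up to 2 passing genes at either end and 2 that do not pass with the highest level, leaving out symbols of predicted genes and clones. The genes printed are a part of those the rule allows, and this part was picked after the effects of leaving out single arrays were known. Of the passing genes the rule allows, 108 of 492 (22.0%) lost their call in some omission of 1 array, against 10 of 146 (6.85%) of those printed, so the printed genes look steadier than the rule's. The same shares were 42.4% against 11.8% at day 0, 26.6% against 2.78% at day 11, 3.45% against 0 over time in control, 17.2% against 0 over time in Nos3-/-, and 51.5% against 26.3% for the difference between these. Under the other alternatives they were 76.1% against 44.1% at day 0.

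The fit was tested on simulated data with the real means and spread and 200 genes changed by known factors. A list of 60 more was raised 1.5-fold. Of genes among the 200 changed 1.5-fold, 75.7% were called at day 0, 70.4% at day 11, 81.7% over time in control, 80.0% over time in Nos3-/- and 53.0% for the difference between genotypes over time, and at 2-fold 90.6%, 92.9%, 96.7%, 85.9% and 75.9%. Unchanged genes made up 5.08%, 5.19%, 4.33%, 4.39% and 6.84% of the simulated calls, the 60 included. The effect of correlation between genes was not tested.

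Alternatives were quantile normalization, centring each array on its median, leaving out genes below the lower tertile or the median of mean level, the mean of a gene's probe sets, leaving out probe sets with the suffixes _x_at and _s_at, eBayes with trend and robust, array weights, only the arrays of the groups compared, the replicate number as a block, and each array left out in turn. After seeing the data, 3 were added, which leave out 3 or 4 arrays that stand apart, or take the mean of the fibroblast list as a covariate among the 16 day 0 arrays. An alternative for values on a linear scale was not run, since the values are log2. Regroupings of the arrays, permutation tests and bootstrap intervals used fixed seeds.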

Results

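Gene expression was measured on 31 Affymetrix arrays of mouse induced pluripotent stem cells (iPSCs), which are fibroblasts returned to an embryo-like state by reprogramming factors, and of the embryoid bodies that grew from them. Nos3 encodes endothelial nitric oxide synthase, the enzyme that makes nitric oxide in blood vessels and heart. At day 0, undifferentiated cells on a layer of growth-arrested embryonic fibroblasts (feeder cells) gave 10 control and 6 Nos3-/- arrays, and at day 11 embryoid bodies gave 9 control and 6 Nos3-/- arrays. Embryoid bodies are cell aggregates that differentiate without added lineage factors. The control cells came from CD1 mice and the Nos3-/- cells from B6.129P2-Nos3tm1unc/J mice, so every genotype difference given here is also a difference between strains, and the 2 cannot be separated. The series title presents the cells as a model of heart disease arising before birth, and the heart gene lists are therefore given in each comparison. The number of arrays limits the precision. Nothing in the labels says that arrays of a group came from separate cultures or clones, so p-values measure the spread between these arrays, which may be technical. The first 2 principal components held 38.7% and 15.2% of the variance.

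The targeted gene was measured by 1 probe set. At day 0 its log2 level was 6.65 ± 0.24 (SD, n = 10) in control and 6.98 ± 0.18 (SD, n = 6) in Nos3-/- cells, a difference of 0.33 (SE 0.11, limma adjusted p = 0.0295). At day 11 the Nos3 level was 7.05 ± 0.21 (SD, n = 9) in control and 6.88 ± 0.14 (SD, n = 6) in Nos3-/- embryoid bodies, a difference of -0.17 that did not pass (limma adjusted p = 0.386). Nos3 rose by 0.40 from day 0 to day 11 in control (limma adjusted p = 0.00128), its change in Nos3-/- was -0.10 (limma adjusted p = 0.538), and the difference between these changes, -0.51, did not pass (limma adjusted p = 0.0861). The labels do not describe the part of the gene that was targeted and the position of the probes is not given in the sources used here, so these levels check nothing about the allele. The day 0 Nos3 call was lost when any 1 of 6 arrays was left out, namely Nos3-/- replicate 2 (adjusted p = 0.0777), 4 (0.0581), 5 (0.0935) or 6 (0.0622), or control replicate 2 (0.0536) or 10 (0.0554). It was also lost in a fit of the day 0 arrays alone (0.33, adjusted p = 0.0548), and with the fibroblast mean as a covariate among them, a setting chosen after seeing the data, the difference was 0.15 (0.767). The interaction term for Nos3 passed without Nos3-/- day 0 replicate 3 (-0.55, adjusted p = 0.0419), with array weights (-0.58, 0.0116) and without 4 arrays that stand apart (-0.57, 0.0473). As another check of the labels, 176 genes that separated the genotypes at day 11 put 0 of the 16 day 0 arrays on the wrong side of their midpoint, and 92 genes from day 0 put 0 of the 15 day 11 arrays there. The list of Nos3 neighbours on chromosome 5 had a median genotype change of 0.01 at day 0 and -0.07 at day 11 over 24 genes, and was called on neither day (camera adjusted p = 0.878 and 0.512).

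**Figure D1:**
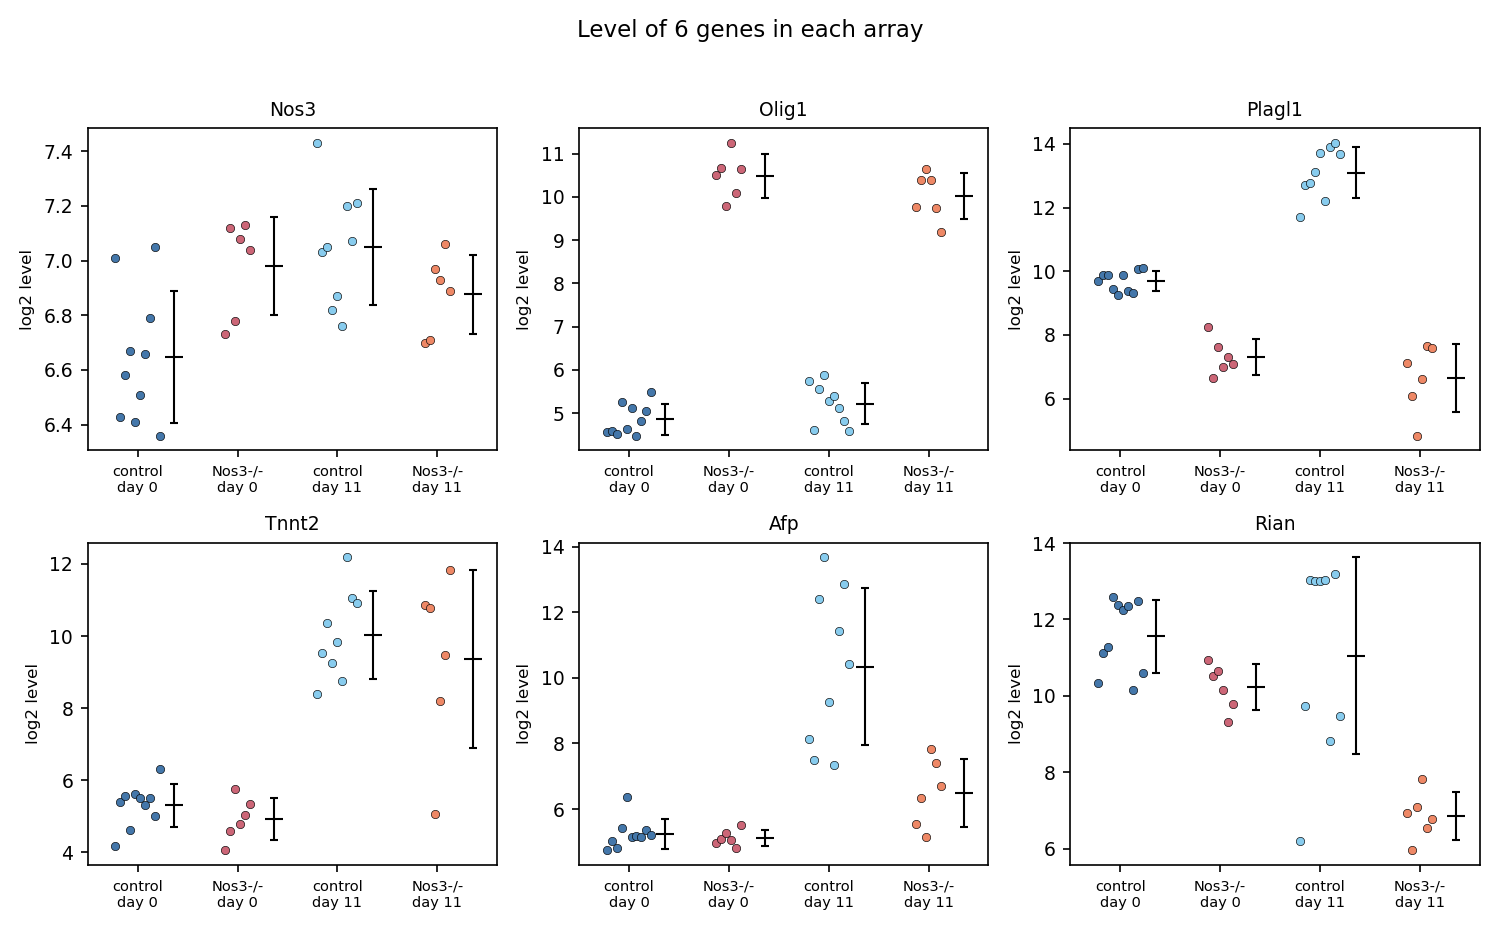
Log2 level (y axis) of Nos3, Olig1, Plagl1, Tnnt2, Afp and Rian on each array, by group on the x axis (control and Nos3-/-, day 0 and day 11), with the mean ± SD of each group. Olig1 lay near 5 on the control arrays and near 10 on the Nos3-/- arrays of both days, and Plagl1 at day 11 averaged 13.09 in control and 6.65 in Nos3-/-.

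The first comparison asked how undifferentiated Nos3-/- cells differed from control cells. Olig1, a transcription factor of oligodendrocyte precursors, was the gene most raised in Nos3-/- cells, at 10.49 ± 0.51 (SD, n = 6) against 4.85 ± 0.36 (SD, n = 10), a log2 change of 5.64 (SE 0.23). Olig2, its neighbour, rose by 3.58, but not on Nos3-/- replicate 3 (3.46, control 3.05 to 3.50). Lower genes, from different lists, included Lhx1 (-3.08), Aplnr, the apelin receptor (-3.05), Isl1, a transcription factor of heart progenitors (-2.68), and Sox17, a transcription factor of endoderm (-2.55). Part of the fibroblast (10 of 37) and extracellular matrix (11 of 33) lists was also lower, and part of the pluripotency (9 of 29) and germline (7 of 22) lists higher. Camera called these 4 lists at its preset correlation and none of them with estimated ones (adjusted p from 0.381 to 0.603). Of 18194 genes tested, 3029 passed an adjusted p of 0.05, with 1669 higher and 1360 lower in Nos3-/-, and 198 of the higher and 156 of the lower genes changed at least 2-fold. Higher calls made up 55.1% of these 3029, and 62.0% when each array was centred on its median. In 344 of the passing genes no Nos3-/- array overlapped a control array, which chance gives in 0.0250% of genes. The count was 1471 without Nos3-/- day 0 replicate 5 and 2012 without replicate 2, and 264 when the per-array mean of the fibroblast list was a covariate among the day 0 arrays, a setting chosen after seeing the data, against 2504 in the same arrays without it.

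Among genes whose values did not overlap between the genotypes at day 0, with predicted genes and clones left out here and below, the highest log2 changes after Olig1 were in Zfp874a, a zinc finger gene (4.28), Trim12a (3.24), Apoa2, an apolipoprotein (2.90), Rpgrip1 (2.39), Dnph1 (2.19), Tex21 (2.12) and Rsl1 (1.99). The lowest were in Ccnb1ip1, a meiotic crossover gene (-3.29), Crxos (-2.60), Atp10d (-2.58), Plagl1, an imprinted zinc finger gene (-2.37), Ap1s3 (-2.29), Ipp (-2.28), Zdbf2 (-2.15) and Cxcl11, a chemokine (-2.07). Adjusted p ranged from 3.67e-18 for Trim12a to 0.00315 for Apoa2. Some of these genes have several probe sets that moved differently. The other probe set of Trim12a changed by -0.05, other probe sets of Rpgrip1 changed by 0.10, 0.01 and 1.25, and the other probe sets of Plagl1 changed by -0.15 and -0.29. Smad2, of the BMP and TGF-beta list, changed by -1.21 on the probe set used and by 2.34 on the other one, and the mean of its probe sets was higher in Nos3-/- cells (0.56), so no direction is given for Smad2. Plagl1 did not pass when probe sets with the suffixes _x_at and _s_at were left out (-0.15, adjusted p = 0.663).

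The fibroblast and feeder list held 37 measured genes, of which 10 fell, 0 rose and 27 did not pass at day 0 (0 and 17 adjusted over the list alone, higher and lower). Its median log2 change was -0.68 (camera adjusted p = 3.46e-07), with an adjusted p of 0.381 under an estimated correlation. Col1a1, which encodes a chain of type I collagen, changed by -1.26 (SE 0.39) and Col5a2, of type V collagen, by -1.24 (SE 0.33). Col1a1 lost its call without Nos3-/- replicate 2 (adjusted p = 0.0505) or 5 (0.101) or control replicate 6 (0.0513) or 10 (0.0522). In the extracellular matrix list 11 of 33 genes fell, 0 rose and 22 did not pass (0 higher and 14 lower over the list alone). The matrix list median was -0.49 (camera adjusted p = 3.61e-06, and 0.381 with an estimated correlation). In the BMP and TGF-beta list 10 of 36 fell, 0 rose and 26 did not pass (1 higher and 13 lower over the list alone). The BMP and TGF-beta list median was -0.39 (camera adjusted p = 2.84e-06, and 0.381 with an estimated correlation). These include Smad2, which has no single direction, and without it 9 of 35 fell, 0 rose and 26 did not pass (1 higher and 12 lower over the list alone, median -0.36, camera adjusted p = 2.85e-05, and 0.381 with an estimated correlation). Immune cell genes, which feeder cultures can also carry, had a median of -0.10, with 1 of 28 lower and 27 not passing (1 lower over the list alone, camera adjusted p = 0.274). That list was called lower without Nos3-/- replicate 1 (-0.39, adjusted p = 0.0153) or 2 (-0.36, 0.0452).

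Several heart and germ layer lists were lower in the same cells, and others were not called. Of 27 cardiac transcription factors, 9 fell, 0 rose and 18 did not pass (0 higher and 9 lower over the list alone). The cardiac factor median was -0.30 (camera adjusted p = 0.000467, and 0.401 with an estimated correlation). Isl1 changed by -2.68 (SE 0.56) and Gata6, a transcription factor of heart and endoderm, by -1.71 (SE 0.47). Gata6 lost its call without Nos3-/- replicate 5 (adjusted p = 0.0535). The valve formation list had 6 of 33 genes lower, 0 higher and 27 not passing (0 higher and 6 lower over the list alone), among them the Notch ligand Jag1 (-1.30). The valve list median was -0.39 (camera adjusted p = 4.5e-05, and 0.381 with an estimated correlation). Genes of the second heart field and outflow tract had 4 of 22 lower, 0 higher and 18 not passing (1 higher and 9 lower over the list alone). The second heart field median was -0.31 (camera adjusted p = 0.00342, and 0.44 with an estimated correlation), or -0.46 without Nos3-/- replicate 3. Contractile and membrane genes of cardiomyocytes had a median of -0.04, with 1 of 42 higher and 2 lower (0 higher and 2 lower over the list alone), and were not called (camera adjusted p = 0.442). Nor were the endothelial (4 of 32 higher and 3 lower, and the same over the list alone, median -0.08, camera adjusted p = 0.878), epicardium (0 of 14 higher and 1 lower, 0 and 0 over the list alone, median -0.09, 0.141, although fry called it lower) and neural ectoderm lists (2 of 29 higher and 3 lower, and the same over the list alone, median 0.03, 0.956). In the definitive endoderm list 9 of 19 fell, 0 rose and 10 did not pass (0 higher and 11 lower over the list alone). The definitive endoderm median was -0.81 (camera adjusted p = 0.000636, and 0.44 with an estimated correlation). Its member Sox17 lost its call without Nos3-/- replicate 1 (-1.82, adjusted p = 0.0615) or 5 (-2.27, 0.0686). In the primitive streak list 6 of 21 fell, 1 rose and 14 did not pass (1 higher and 9 lower over the list alone), led by Lhx1 and by Gsc, a homeobox gene of the organizer (-2.25). Its median was -0.36 (camera adjusted p = 0.008, and 0.401 with an estimated correlation). In the day 0 arrays alone the fibroblast covariate took Col1a1 from -1.26 (SE 0.35) to -0.37 (SE 0.33) and Col5a2 from -1.24 (SE 0.28) to -0.58 (SE 0.28), and neither passed. Lhx1 went from -3.08 (SE 0.84) to -2.93 (SE 1.13), Gsc from -2.25 (SE 0.63) to -2.04 (SE 0.85), Gata6 from -1.71 (SE 0.50) to -1.65 (SE 0.67), Sox17 from -2.55 (SE 0.77) to -2.67 (SE 1.04), Aplnr from -3.05 (SE 0.67) to -2.57 (SE 0.88) and Jag1 from -1.30 (SE 0.26) to -1.01 (SE 0.34). These 6 lost their calls as errors grew, with 0.78 to 1.05 of the change left. Adjusted p was from 0.223 for Jag1 to 0.771 for Col1a1, while Isl1 passed (-3.19, adjusted p = 0.0035). The valve formation (-0.10, adjusted p = 0.422) and second heart field (-0.02, 0.347) lists were not called with the covariate.

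Pluripotency genes were higher at day 0, with 9 of 29 raised, 0 lowered and 20 not passing (11 higher and 0 lower over the list alone) and a median of 0.66 (camera adjusted p = 0.000826, and 0.603 with an estimated correlation). Fbxo15, a marker used to report pluripotency, rose by 2.56 (SE 0.50). The list median was 1.23 without Nos3-/- replicate 3, whose mean over the list was 8.67 against a group mean of 10.54 ± 0.94 (SD, n = 6). Germline genes had 7 of 22 raised, 0 lowered and 15 not passing (9 higher and 0 lower over the list alone), including Stag3, a meiotic cohesin (2.25), and Stk31 (2.14). The germline median was 0.53 (camera adjusted p = 0.00137, and 0.484 with an estimated correlation), or 0.25 without Nos3-/- replicate 5. Formative and primed epiblast genes went the other way, with 0 of 17 raised, 2 lowered and 15 not passing (0 higher and 2 lower over the list alone). The formative median was -0.44 (camera adjusted p = 0.0228, and 0.603 with an estimated correlation). That call was lost without Nos3-/- replicate 5 (-0.19, adjusted p = 0.318) or 6 (-0.47, 0.055). Oxidative phosphorylation genes had 7 of 41 raised, 0 lowered and 34 not passing (11 higher and 0 lower over the list alone), among them Ndufv1 of complex I (0.36). The oxidative phosphorylation median was 0.12 (camera adjusted p = 0.000826, and 0.484 with an estimated correlation). Cell cycle genes had 7 of 33 raised, 1 lowered and 25 not passing (10 higher and 2 lower over the list alone). The cell cycle median was 0.11 (camera adjusted p = 0.0295, and 0.635 with an estimated correlation). The cell cycle call was lost without Nos3-/- replicate 1 (0.10, adjusted p = 0.129) or 4 (0.07, 0.187) or control replicate 6 (0.11, 0.0763), and after quantile normalization (0.10, 0.0892), and its median was 0.19 without Nos3-/- replicate 3. With the fibroblast covariate the pluripotency (0.20, adjusted p = 0.135), germline (0.16, 0.217), formative (-0.29, 0.0858), oxidative phosphorylation (0.03, 0.347) and cell cycle (0.01, 0.733) lists were not called. Fbxo15 then went from 2.56 (SE 0.56) in the same arrays to 1.497 (SE 0.63), Stag3 from 2.25 (SE 0.48) to 1.76 (SE 0.63), Stk31 from 2.14 (SE 0.55) to 1.41 (SE 0.68) and Ndufv1 from 0.36 (SE 0.09) to 0.24 (SE 0.11), and none of the 4 passed (adjusted p from 0.277 to 0.497). In all, camera called 19 of 41 lists at day 0, 4 higher and 15 lower. With estimated correlations it called 0, with 1 list at an unadjusted p under 0.05, and the rotation test fry called 18.

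The genes printed by name throughout were chosen from a larger set that a rule fixed in advance allows, after the effect of leaving out single arrays had been seen, and so they look steadier than the set. At day 0, 39 of 92 passing genes of the full set (42.4%) lost their call when some single array was left out, against 4 of 34 named ones (11.8%). Under the other alternatives, the fibroblast covariate among them, 70 of the 92 (76.1%) and 15 of the 34 (44.1%) lost a call. Dppa3, Tdgf1, Ndufs4, Vim, Bmp2, Cer1 and Col4a1 belong to that set and are not described further.

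**Figure D2:**
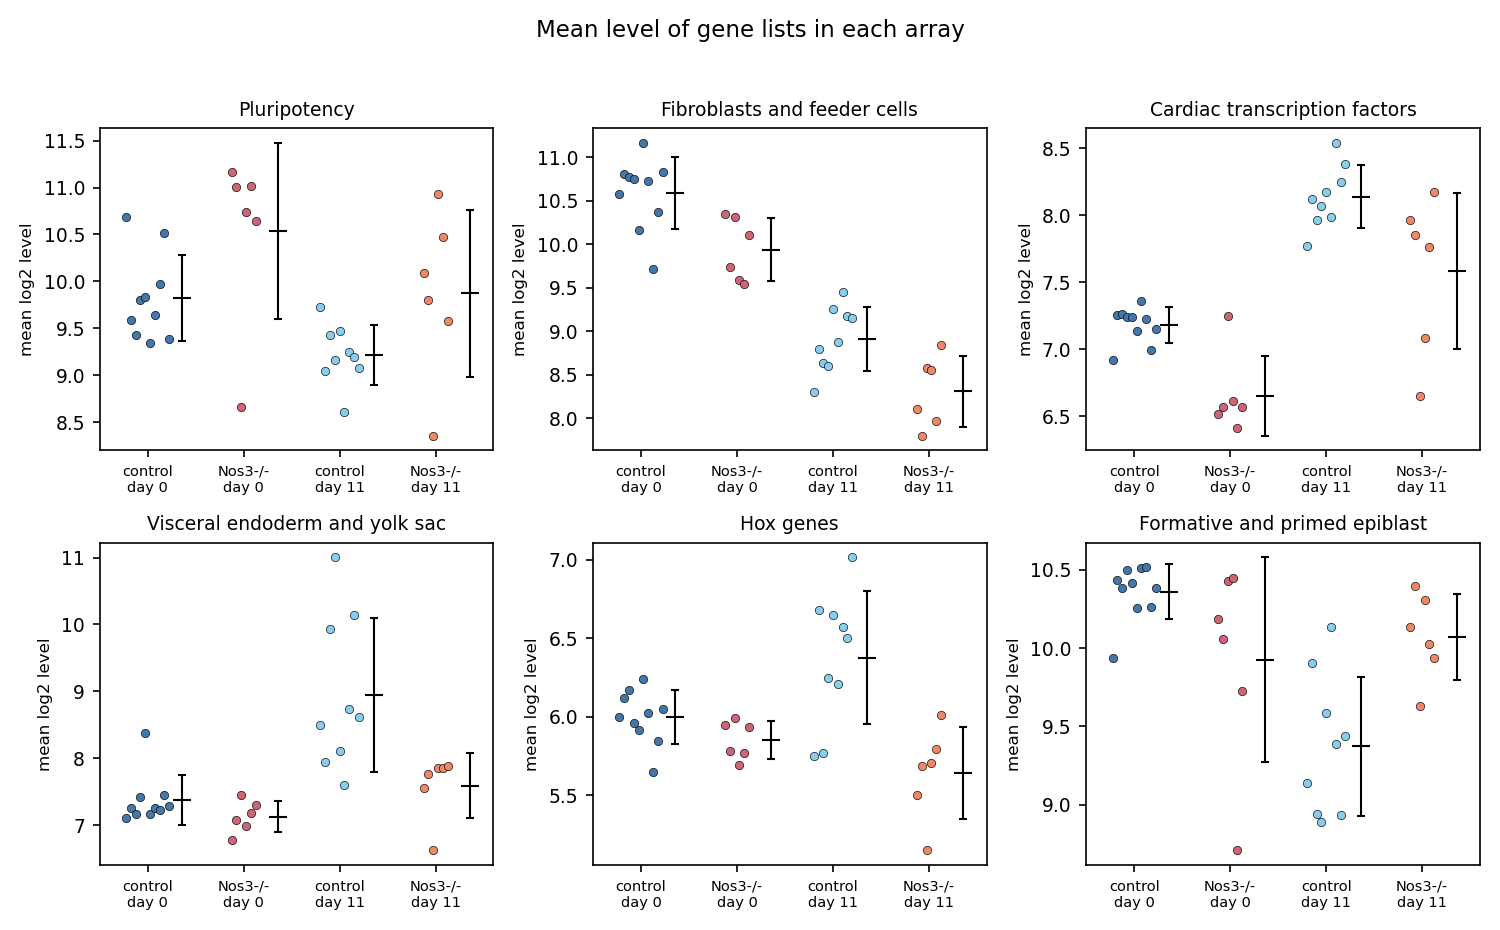
Mean log2 level over the genes of 6 lists (pluripotency, fibroblasts and feeder cells, cardiac transcription factors, yolk sac, Hox, formative epiblast) on each array (y axis), by group on the x axis, with the mean ± SD of each group. The fibroblast list averaged 10.59 in control and 9.94 in Nos3-/- cells at day 0 and 8.91 and 8.31 at day 11, and the yolk-sac list at day 11 averaged 8.95 in control and 7.59 in Nos3-/-.

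The next comparison was between embryoid bodies of the 2 genotypes after 11 days of differentiation. Part of the yolk-sac (12 of 29), Hox (13 of 26) and valve formation (14 of 33) lists was lower in Nos3-/-, and part of the formative epiblast (6 of 17) and pluripotency (8 of 29) lists higher. Camera called these 5 lists at its preset correlation and none of them with estimated ones (adjusted p from 0.294 to 0.558). Afp, the fetal serum protein made by visceral endoderm, averaged 6.50 ± 1.03 (SD, n = 6) in Nos3-/- against 10.34 ± 2.40 (SD, n = 9) in control, a log2 change of -3.84 (SE 0.71). Plagl1 had the largest fall, from 13.09 ± 0.81 (SD, n = 9) to 6.65 ± 1.07 (SD, n = 6), a change of -6.44 (SE 0.36), and its other probe sets changed by -1.70 and -3.24. Of 18194 genes, 1764 passed, 802 higher and 962 lower in Nos3-/-, with 152 and 240 of them changed at least 2-fold. Which direction has more genes depends on the scaling, since higher calls made up 45.5% here and 50.4% after quantile normalization (911 higher and 897 lower). Nos3-/- and control arrays did not overlap in 458 of the passing genes, which chance gives in 0.0400% of genes. Leaving out single arrays gave counts from 1345 to 2295, array weights gave 3939, and leaving out genes below the median of mean level gave 1121.

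Olig1 (4.80), Zfp874a (3.73), Rpgrip1 (2.58), Fbxo15 (2.54) and Trim12a (2.50) were again among the genes most raised. They were joined by Fgf4, a growth factor of pluripotent cells (2.85), Ang, the ribonuclease angiogenin (2.81), and Sema3c, a guidance cue used in the outflow tract of the heart (2.63). Ang has 3 probe sets, and without those with the suffixes _x_at and _s_at its change was -0.069, so its direction depends on the probe set. The lowest non-overlapping genes after Plagl1 were S100g, a calcium-binding protein (-3.85), Postn, the matrix protein periostin (-3.76), Ccnb1ip1 (-3.64), Rbp4, the retinol carrier (-3.43), Tmem87a (-3.16), Glipr1 (-3.11) and Col1a1 (-2.91). Tmem87a had the lowest adjusted p of the named genes (1.29e-21), with levels of 6.88 ± 0.15 (SD, n = 6) and 10.04 ± 0.08 (SD, n = 9). Nnt, a mitochondrial transhydrogenase truncated in some C57BL/6 substrains, changed by -0.84 on this day and -0.85 at day 0. Wdfy1 changed by -2.13 and -1.78. Both belong to the list of genes with known strain differences, which was not called on either day, with 4 of 15 higher and 4 lower at day 0 and 4 higher and 3 lower at day 11 (5 higher and 4 lower over the list alone on both days, camera adjusted p = 0.749 and 0.893).

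Yolk-sac and visceral endoderm genes had 12 of 29 lower, 0 higher and 17 not passing at day 11 (0 higher and 19 lower over the list alone). The yolk-sac median was -1.06 (camera adjusted p = 8.64e-10, and 0.416 with an estimated correlation). Cubn, a receptor of absorptive endoderm, changed by -4.15 (SE 0.83), Afp by -3.84 and Rbp4 by -3.43. Without control day 11 replicate 4 the median was -0.65. Hox genes, which pattern the body axis, had 13 of 26 lower, 0 higher and 13 not passing (0 higher and 14 lower over the list alone), including Hoxd1 (-2.14) and Hoxa9 (-1.90). The Hox median was -0.79 (camera adjusted p = 7.27e-11, and 0.294 with an estimated correlation). Imprinted genes had 7 of 29 lower, 0 higher and 22 not passing (0 higher and 11 lower over the list alone). The imprinted median was -0.60 (camera adjusted p = 1.35e-07, and 0.294 with an estimated correlation), or -0.37 without Nos3-/- replicate 3. Rian, a non-coding RNA of the Dlk1 locus, was at 6.86 ± 0.62 (SD, n = 6) in Nos3-/- against 11.06 ± 2.57 (SD, n = 9) in control, a change of -4.20. The control arrays themselves ran from 6.21 to 13.19 for Rian.

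The heart-related lists at day 11 were each tested against other genes and not against each other. Valve formation genes had 14 of 33 lower, 0 higher and 19 not passing (1 higher and 18 lower over the list alone), led by Postn. The valve list median was -0.58 (camera adjusted p = 3.94e-09, and 0.294 with an estimated correlation). Cardiac transcription factors had 9 of 27 lower, 1 higher and 17 not passing (2 higher and 11 lower over the list alone), including Gata6 (-2.01) and Tbx20 (-1.99). The cardiac factor median was -0.34 (camera adjusted p = 0.000399, and 0.543 with an estimated correlation). The second heart field list was not called, with 1 of 22 higher, 5 lower and 16 not passing (1 higher and 6 lower over the list alone) and a median of -0.27 (camera adjusted p = 0.169). It was called lower without Nos3-/- replicate 6 (-0.40, adjusted p = 0.0363) or control replicate 1 (-0.42, 0.0495). Of the 42 contractile and membrane genes of cardiomyocytes, 2 fell, 0 rose and 40 did not pass (0 higher and 2 lower over the list alone). The contractile list median was -0.22 (camera adjusted p = 0.125). The 2 were Ankrd1, a stress-responsive sarcomere protein (-1.79), and Ryr2, the calcium release channel (-1.29). Gja1 (0.19, adjusted p = 0.374) and Tpm1 (-0.14, adjusted p = 0.764), the brightest of the rest, did not pass. The contractile list was called lower without Nos3-/- replicate 6 (-0.39, adjusted p = 0.0035) or control replicate 1 (-0.32, 0.0403) or 6 (-0.28, 0.0387). Ryr2 lost its call without Nos3-/- replicate 3 (adjusted p = 0.0524), 4 (0.0551) or 5 (0.0507), and in a fit of the day 11 arrays alone (0.0718). The nitric oxide list was not called, with 1 of 25 higher, 2 lower and 22 not passing (2 higher and 2 lower over the list alone, camera adjusted p = 0.846). Its passing members were Cav1, which binds the Nos3 protein (1.09), Gch1, which makes the cofactor of nitric oxide synthases (-1.20), and Gucy1b1, a subunit of the nitric oxide receptor (-1.91).

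Fibroblast genes had 10 of 37 lower, 4 higher and 23 not passing (6 higher and 15 lower over the list alone), among them Col1a1 and Col5a2 (-2.89). The fibroblast median was -0.55 (camera adjusted p = 0.000109, and 0.558 with an estimated correlation). Pluripotency genes had 8 of 29 higher, 0 lower and 21 not passing (10 higher and 1 lower over the list alone). The pluripotency median was 0.62 (camera adjusted p = 1.6e-05, and 0.558 with an estimated correlation). That median was 0.24 without Nos3-/- replicate 4 and 0.39 without replicate 5. Formative and primed epiblast genes had 6 of 17 higher, 0 lower and 11 not passing (8 higher and 0 lower over the list alone), including Lefty1, a Nodal antagonist (2.25), and Pou3f1 (1.96). The formative median was 0.58 (camera adjusted p = 1.61e-05, and 0.416 with an estimated correlation). Targets of p53 and cell death genes had 6 of 20 higher, 1 lower and 13 not passing (8 higher and 1 lower over the list alone), including Pmaip1, which encodes the pro-death protein Noxa (0.85). The p53 list median was 0.28 (camera adjusted p = 0.000467, and 0.416 with an estimated correlation). Camera called 17 of 41 lists, 4 higher and 13 lower, 0 with estimated correlations (4 at an unadjusted p under 0.05), and fry called 13. Without Nos3-/- day 11 replicate 3, an array with a yolk-sac mean of 6.63, 6 lower lists lost their call, namely primitive streak (adjusted p = 0.165), smooth muscle (0.208), epicardium (0.0723), immune cells (0.118), VEGF and angiopoietin (0.138), whose member Tek, the angiopoietin receptor, changed by -1.27, and extracellular matrix (0.0668).

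Between the genotype differences of the 2 days, which share no arrays, 684 genes passed on both, and 676 of them in the same direction. Of these, 384 were higher and 292 lower in Nos3-/- on both days, where independent lists would share 73.6 and 71.9, and 8 genes went opposite ways. Across genes, which are not independent replicates, the log2 changes of the days had a correlation of 0.504. Olig1, Zfp874a, Trim12a, Rpgrip1 and Fbxo15 were raised, and Plagl1, Ccnb1ip1, Wdfy1, Nnt, Gata6, Col1a1 and Col5a2 lowered, on both days. Smad2 changed by -1.32 at day 11 on the probe set used, 3.16 on the other and 0.92 in their mean, with no single direction. With it the BMP and TGF-beta list was called lower (median -0.14, camera adjusted p = 0.0126), without it not (-0.10, 0.0522), and neither with estimated correlations.

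**Figure D3:**
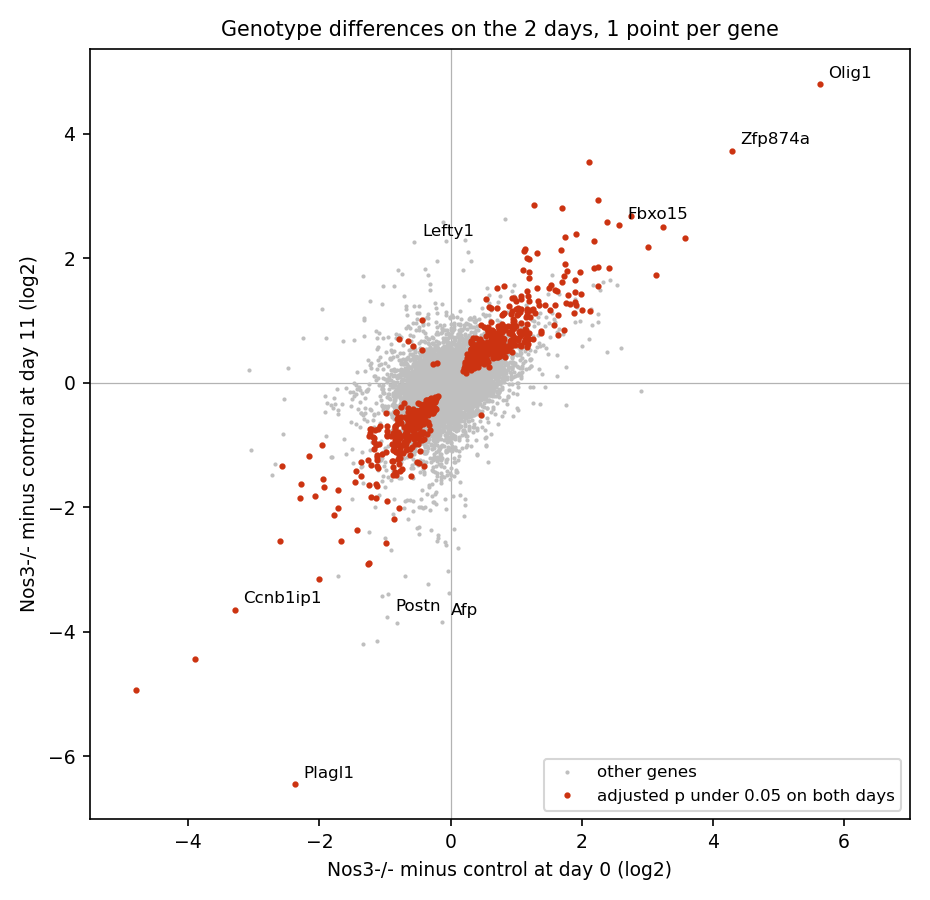
Log2 change between Nos3-/- and control at day 0 (x axis) and at day 11 (y axis), 1 point per gene, for all 18194 genes tested, with genes passing on both days in red. Of 684 such genes, 676 lie in the quadrants where both changes have the same sign, and Olig1 lies at 5.64 and 4.80.

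Over the 11 days in control, part of the contractile (21 of 42, 3 lowered) and yolk-sac (21 of 29, 3 lowered) lists rose. Part of the fibroblast (25 of 37, 6 raised), immune cell (22 of 28, 1 raised) and formative epiblast (10 of 17, 2 raised) lists fell. Camera called these 5 lists at its preset correlation and none of them with estimated ones (adjusted p from 0.369 to 0.464). Feeder cells are described at day 0 only. Changes over time, and genotype differences in these changes, may thus include feeder loss. Tnnt2, which encodes cardiac troponin T, rose from 5.30 ± 0.59 (SD, n = 10) to 10.03 ± 1.21 (SD, n = 9), a log2 change of 4.73 (SE 0.58). Afp rose by 5.09, Hbb-bh1, an embryonic globin, by 4.99 and Hand2, a transcription factor of heart development, by 4.27. The primitive erythroid list as a whole was not called, with 8 of 18 raised, 3 lowered and 7 not passing (8 higher and 3 lower over the list alone, median 0.13, camera adjusted p = 0.0745). It was called higher by fry, and by camera without control day 11 replicate 1 (0.13, adjusted p = 0.0383) or 3 (0.16, 0.0257). Lyz2, the lysozyme of macrophages, fell by 6.12, from 12.71 ± 0.81 (SD, n = 10) to 6.59 ± 0.64 (SD, n = 9). In control, 6227 genes passed, 2919 higher and 3308 lower, with 393 and 629 changed at least 2-fold, and 1185 of them did not overlap between days (chance share 0.00217%). Higher calls made up 46.9% of these 6227, and 38.0% when each array was centred on its median. The count was 3835 with genes below the median of mean level left out. Other non-overlapping genes at the top were Tdo2 (5.05), Ttr, the thyroxine carrier of yolk sac and liver (4.11), Hapln1 (4.08) and Dlk1 (4.04), and at the bottom were Lyz1 (-6.43), Mmp13 (-6.10), Mgp (-6.09), Tm4sf1 (-5.91), Mmp3 (-5.82), Il6 (-5.81) and Mcpt8 (-5.68).

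Cardiac transcription factors had 13 of 27 raised, 0 lowered and 14 not passing over time in control (14 higher and 0 lower over the list alone), including Tbx20 (3.99). The cardiac factor median was 0.62 (camera adjusted p = 1.59e-06, and 0.369 with an estimated correlation). Contractile and membrane genes had 21 of 42 raised, 3 lowered and 18 not passing (22 higher and 3 lower over the list alone), including Ttn, the giant sarcomere protein titin (4.00). The contractile list median was 0.80 (camera adjusted p = 5.36e-05, and 0.436 with an estimated correlation). Valve formation genes had 14 of 33 raised, 5 lowered and 14 not passing (16 higher and 6 lower over the list alone). The valve list median was 0.31 (camera adjusted p = 0.000551, and 0.436 with an estimated correlation). Second heart field genes had 8 of 22 raised, 2 lowered and 12 not passing (8 higher and 2 lower over the list alone). The second heart field median was 0.45 (camera adjusted p = 0.0109, and 0.464 with an estimated correlation). Yolk-sac genes had 21 of 29 raised, 3 lowered and 5 not passing (21 higher and 3 lower over the list alone), among them Apob (4.43). The yolk-sac median was 1.33 (camera adjusted p = 5.47e-07, and 0.436 with an estimated correlation). The endothelial list had 16 of 32 raised, 1 lowered and 15 not passing (17 higher and 1 lower over the list alone), among them Tek (2.28). The endothelial median was 0.61 (camera adjusted p = 2.26e-05, and 0.375 with an estimated correlation). Imprinted genes had 16 of 29 raised, 2 lowered and 11 not passing (18 higher and 2 lower over the list alone), among them Igf2 (3.52). The imprinted median was 0.72 (camera adjusted p = 3.16e-07, and 0.369 with an estimated correlation). Hox genes had 10 of 26 raised, 1 lowered and 15 not passing (10 higher and 2 lower over the list alone), led by Hoxd1 (3.10). The Hox median was 0.13 (camera adjusted p = 0.0109, and 0.57 with an estimated correlation). The Hox median was 0.26 without control day 11 replicate 1, 0.27 without replicate 3, 0.20 without replicate 6, 0.08 without replicate 8, 0.03 without replicate 9, and 0.07 without control day 0 replicate 8.

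Lists of fibroblast, immune cell, oxidative stress, formative and pluripotency genes were lower over the same days in control, and which cells these transcripts came from was not tested. The fibroblast list had 25 of 37 lowered, 6 raised and 6 not passing (7 higher and 26 lower over the list alone), among them S100a4 (-5.43). The fibroblast median was -1.66 (camera adjusted p = 7.81e-10, and 0.369 with an estimated correlation). Immune cell genes had 22 of 28 lowered, 1 raised and 5 not passing (1 higher and 23 lower over the list alone), among them Ctss, a lysosomal protease of macrophages (-4.70). The immune median was -1.49 (camera adjusted p = 1.17e-08, and 0.369 with an estimated correlation). Oxidative stress genes had 15 of 25 lowered, 2 raised and 8 not passing (3 higher and 15 lower over the list alone), among them Nqo1 (-1.97). The oxidative stress median was -0.40 (camera adjusted p = 0.00058, and 0.369 with an estimated correlation). Formative epiblast genes had 10 of 17 lowered, 2 raised and 5 not passing (2 higher and 10 lower over the list alone), led by Lefty1 (-3.93) and Lefty2 (-3.64). The formative median was -0.69 (camera adjusted p = 0.00309, and 0.464 with an estimated correlation). Pluripotency genes had 9 of 29 lowered, 1 raised and 19 not passing (1 higher and 11 lower over the list alone), among them Nr0b1 (-2.04) and Fgf4 (-1.90). The pluripotency median was -0.64 (camera adjusted p = 0.0165, and 0.736 with an estimated correlation). Camera called 18 of 41 lists, 11 higher and 7 lower, 0 with estimated correlations (4 at an unadjusted p under 0.05), and fry called 26.

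Over the same days in Nos3-/-, part of the contractile list rose (14 of 42, 2 lowered). Part of the fibroblast (28 of 37, 1 raised) and immune cell (18 of 28, 1 raised) lists fell. Camera called these 3 lists at its preset correlation and none of them with estimated ones (adjusted p from 0.329 to 0.427). Tnnt2 rose from 4.92 ± 0.59 (SD, n = 6) to 9.36 ± 2.46 (SD, n = 6), a log2 change of 4.44 (SE 0.72), with Ttn at 3.92 and Tnni1, a troponin of fetal heart and slow muscle, at 2.93. Nos3-/- day 11 replicate 3 showed no rise in Tnnt2, at 5.05 against 8.20 to 11.82 on the other 5 arrays and 4.05 to 5.75 at day 0, and the change was 5.30 without it. Lyz2 changed by -6.55 and Ccl2, a chemokine of fibroblasts and macrophages, by -4.13. The number passing was 5658, 2359 higher and 3299 lower, with 341 and 509 changed at least 2-fold, and 1384 did not overlap between days (chance share 0.216%). Higher calls made up 41.7% of these 5658, and 30.9% when each array was centred on its median. The count was 3679 with the Nos3-/- arrays alone and 3756 with genes below the median of mean level left out. Further genes at the top without overlap were Hapln1 (3.97), Igfbp5 (3.88), Fbn2 (3.76), Bmp5 (3.08), Meis2 (2.90) and Prtg (2.62). Igfbp5 changed by -0.033 without probe sets with the suffixes _x_at and _s_at, so its direction depends on the probe set. Those at the bottom included Lyz1 (-7.26), Tslp (-5.38), Ctss (-5.21), Il6 (-4.80), Clec4n (-4.69), Mcpt8 (-4.55) and Ms4a7 (-4.51). Between the time courses of the genotypes, which share no arrays, 3280 genes passed in both, 1503 higher and 1749 lower in both (378 and 600 for independent lists), and 28 went opposite ways, with a correlation across genes of 0.770.

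Cardiac transcription factors had 13 of 27 raised, 0 lowered and 14 not passing over time in Nos3-/- (15 higher and 0 lower over the list alone), including Hand2 (2.77) and Tbx20 (2.44). The cardiac factor median was 0.76 (camera adjusted p = 1.75e-07, and 0.329 with an estimated correlation). Contractile and membrane genes had 14 of 42 raised, 2 lowered and 26 not passing (16 higher and 2 lower over the list alone). The contractile list median was 0.23 (camera adjusted p = 0.000526, and 0.427 with an estimated correlation). Valve formation genes had 13 of 33 raised, 6 lowered and 14 not passing (13 higher and 6 lower over the list alone). The valve list median was 0.26 (camera adjusted p = 0.00671, and 0.454 with an estimated correlation). That median was 0.11 without Nos3-/- day 0 replicate 5, and 0.39 and 0.17 without Nos3-/- day 11 replicates 3 and 6. Second heart field genes had 10 of 22 raised, 0 lowered and 12 not passing (10 higher and 0 lower over the list alone). The second heart field median was 0.55 (camera adjusted p = 0.000156, and 0.355 with an estimated correlation). The endothelial list had 9 of 32 raised, 0 lowered and 23 not passing (9 higher and 0 lower over the list alone), among them Aplnr (3.98). The endothelial median was 0.37 (camera adjusted p = 0.000694, and 0.415 with an estimated correlation). Imprinted genes had 13 of 29 raised, 3 lowered and 13 not passing (14 higher and 3 lower over the list alone), among them Igf2 (3.12), Dlk1 (2.88) and, in the other direction, Rian (-3.37). The imprinted median was 0.57 (camera adjusted p = 0.00038, and 0.355 with an estimated correlation), or 0.37 without Nos3-/- day 0 replicate 3. Dlk1 did not pass without probe sets of the suffixes _x_at and _s_at (0.06, adjusted p = 0.77), and Rian did not pass as the mean of its probe sets (-1.62, adjusted p = 0.0939).

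Fibroblast genes had 28 of 37 lowered, 1 raised and 8 not passing in Nos3-/- (1 higher and 29 lower over the list alone). The fibroblast median was -1.53 (camera adjusted p = 7.48e-11, and 0.329 with an estimated correlation). Immune cell genes had 18 of 28 lowered, 1 raised and 9 not passing (1 higher and 19 lower over the list alone). The immune median was -1.53 (camera adjusted p = 6.63e-09, and 0.329 with an estimated correlation). Oxidative phosphorylation genes had 16 of 41 lowered, 0 raised and 25 not passing (0 higher and 22 lower over the list alone), among them Sdhd (-0.44). The oxidative phosphorylation median was -0.21 (camera adjusted p = 0.000306, and 0.427 with an estimated correlation). Yolk-sac genes had 6 of 29 raised, 1 lowered and 22 not passing (5 higher and 1 lower over the list alone), among them Apob (2.60), with a median of 0.28 that was not called (camera adjusted p = 0.0864) but was called without Nos3-/- day 11 replicate 3 (0.32, adjusted p = 0.0261). Pluripotency genes had 4 of 29 lowered, 0 raised and 25 not passing (0 higher and 3 lower over the list alone). The pluripotency median was -0.63 (camera adjusted p = 0.0864). They were called lower without Nos3-/- day 0 replicate 3 (-0.98, adjusted p = 0.000592), day 11 replicate 4 (-0.78, 0.0102) or day 11 replicate 5 (-0.70, 0.0436). Pou5f1, the core pluripotency factor Oct4, changed by -0.32 without passing (adjusted p = 0.251) and passed without day 0 replicate 3 (-0.55, adjusted p = 0.0156). Lefty2 fell by 2.02. Formative epiblast genes (4 of 17 raised, 3 lowered, and the same counts over the list alone, median 0.23, camera adjusted p = 0.173) and Hox genes (0 of 26 raised, 5 lowered, 0 and 4 over the list alone, median -0.20, camera adjusted p = 0.378) were not called. Camera called 19 of 41 lists, 14 higher and 5 lower, 0 with estimated correlations (6 at an unadjusted p under 0.05), and fry called 22.

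The last comparison tested whether the change from day 0 to day 11 differed between genotypes, as the change in Nos3-/- minus that in control. Of the formative epiblast list, 3 of 17 genes had a higher change in Nos3-/- and 14 did not pass, and camera called the list at its preset correlation and not with an estimated one (adjusted p = 0.246). Lefty1, 1 of the 3, fell from 13.31 ± 0.22 (SD, n = 10) to 9.39 ± 0.82 (SD, n = 9) in control and stood at 12.75 ± 0.84 (SD, n = 6) and 11.64 ± 0.70 (SD, n = 6) in Nos3-/-, a difference of 2.81 (SE 0.47). Plagl1 averaged 9.69 and 13.09 in control, and 7.32 and 6.65 in Nos3-/-, a difference of -4.07 (SE 0.50). Tdo2 (-3.35), Postn (-2.79), Hoxd1 (-2.34), Prdm6 (-1.95) and Adamts20 (-1.94) also had a lower change in Nos3-/-. Genes with a higher change in Nos3-/- included Grem1, a BMP antagonist (2.62), Fzd5, a Wnt receptor (2.37), Cav1 (1.76), Pmaip1 (0.93) and Wnt6 (0.77), and further lower ones were Tek (-1.84), Phlda2, an imprinted gene (-1.54), and Hey2, a Notch target in the heart (-1.47). In total 225 genes passed, 95 higher and 130 lower, with 47 and 43 at 2-fold or more. Higher calls made up 42.2% of these 225, 46.5% after quantile normalization and 36.4% when each array was centred on its median. This count moved by over 1.5 times without Nos3-/- day 0 replicate 2 (112), 3 (745), 5 (88) or 6 (119), Nos3-/- day 11 replicate 1 (121), 2 (149), 3 (620) or 6 (148), control day 0 replicate 2 (147) or 6 (143), or control day 11 replicate 8 (134). It was 1590 with array weights, and 460 and 1085 without 3 or 4 arrays that stand apart.

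Other genes with a higher change in Nos3-/- depended on single arrays. Fgf5, a marker of primed epiblast, had a difference of 3.05 (adjusted p = 0.0423) and lost its call in 22 of the 31 omissions. Adjusted p for Fgf5 was then 0.052, 0.0616, 0.0932 and 0.0733 without Nos3-/- day 0 replicates 1, 2, 5 and 6, and 0.0795, 0.0677, 0.066, 0.0609 and 0.0657 without Nos3-/- day 11 replicates 1, 2, 4, 5 and 6. It was 0.063, 0.0612, 0.0571, 0.0542, 0.0592, 0.051 and 0.055 without control day 0 replicates 2, 3, 4, 6, 7, 8 and 10, and 0.0521, 0.0564, 0.0519, 0.0564, 0.0698 and 0.0589 without control day 11 replicates 1, 3, 4, 5, 8 and 9. Mmp13 (2.50, adjusted p = 0.0396) lost its call in 14 omissions, with adjusted p of 0.0732, 0.0611, 0.0797 and 0.0615 without Nos3-/- day 0 replicates 2, 4, 5 and 6, and 0.0501 and 0.0627 without Nos3-/- day 11 replicates 1 and 4. For Mmp13 it was 0.0507, 0.0553, 0.0542 and 0.059 without control day 0 replicates 2, 4, 6 and 7, and 0.0535, 0.0519, 0.0569 and 0.0616 without control day 11 replicates 3, 4, 5 and 8. Ppbp, a platelet chemokine (2.42, adjusted p = 0.0336), lost it in 8, with 0.0515, 0.0784 and 0.0603 without Nos3-/- day 0 replicates 2, 5 and 6, 0.0506, 0.0502 and 0.0506 without control day 0 replicates 2, 3 and 6, and 0.0534 and 0.0639 without Nos3-/- day 11 replicates 4 and 6. Ereg, a growth factor of the EGF family (2.58), did not pass without Nos3-/- day 0 replicate 5 (adjusted p = 0.0609) or 6 (0.0509), nor Fzd5 without replicate 5 (0.053).

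In the lists, formative epiblast genes had 3 of 17 with a higher change in Nos3-/-, 0 lower and 14 not passing (11 higher and 0 lower over the list alone), and a median difference of 0.89 (camera adjusted p = 6.83e-10, and 0.246 with an estimated correlation). Surface ectoderm genes had 3 of 21 higher, 0 lower and 18 not passing (9 higher and 1 lower over the list alone). The surface ectoderm median was 0.77 (camera adjusted p = 1.91e-06, and 0.167 with an estimated correlation). Hox genes had 3 of 26 lower, 0 higher and 23 not passing (0 higher and 8 lower over the list alone). The Hox median was -0.43 (camera adjusted p = 3.5e-06, and 0.663 with an estimated correlation), or -0.27 without control day 11 replicate 9. Targets of p53 had 1 of 20 higher, 0 lower and 19 not passing (9 higher and 1 lower over the list alone). The p53 list median was 0.34 (camera adjusted p = 5.02e-05, and 0.275 with an estimated correlation). Yolk-sac genes had 0 of 29 passing (0 higher and 9 lower over the list alone). The yolk-sac median was -1.10 (camera adjusted p = 7.52e-05, and 0.94 with an estimated correlation). Oxidative phosphorylation genes had 0 of 41 passing (0 and 0 over the list alone). The oxidative phosphorylation median was -0.14 (camera adjusted p = 0.000223, and 0.94 with an estimated correlation), or -0.09 without Nos3-/- day 11 replicate 3. Notch pathway genes had 1 of 25 higher, 1 lower and 23 not passing (2 higher and 1 lower over the list alone). The Notch median was 0.20 (camera adjusted p = 0.018, and 0.275 with an estimated correlation), or 0.12 without Nos3-/- day 0 replicate 5. Definitive endoderm genes had 0 of 19 passing (4 higher and 1 lower over the list alone). The definitive endoderm median was 0.69 (camera adjusted p = 0.018, and 0.94 with an estimated correlation). That call was lost without Nos3-/- day 0 replicate 1 (0.36, adjusted p = 0.204) or 5 (0.56, 0.054), control day 0 replicate 5 (0.69, 0.0516), or Nos3-/- day 11 replicate 2 (0.64, 0.0593) or 5 (0.62, 0.0588). Cardiac transcription factors (median -0.04, camera adjusted p = 0.871) and contractile genes (median -0.09, camera adjusted p = 0.684) were not called, with 1 higher and 1 lower of 27 and 0 of 42 passing (3 higher and 3 lower, and 0 and 0, over the list alone). Nor were valve formation genes (0 of 33 higher and 3 lower, 0 and 5 over the list alone, median -0.10, camera adjusted p = 0.295) or second heart field genes (1 of 22 higher and 0 lower, 1 and 0 over the list alone, median 0.15, camera adjusted p = 0.197), although the last were called without Nos3-/- day 11 replicate 3 (0.26, adjusted p = 0.0201). Camera called 8 of 41 lists, 5 higher and 3 lower, 0 with estimated correlations (4 at an unadjusted p under 0.05), and fry called 2.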

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

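Of the tests in this part, that of sequence differences under the probes was set out before its result was seen, although Smad2, Trim12a and Rpgrip1, whose probe sets differ, had been seen by then, and the regroupings of arrays and the tests of the other explanations were set out only after the results.

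In 100 regroupings of the arrays of each comparison, fitted with those arrays alone and the real grouping included, no other gave as many genes. This argues against chance for all 5 counts if arrays are independent, which is not known. For the difference between genotypes over time, the effects of genotype and day were kept and the residuals of the fit without an interaction were exchanged within each day. The real counts and the highest others were 2504 and 641 at day 0, 1473 and 0 at day 11, 6795 and 4434 over time in control, 3679 and 0 over time in Nos3-/-, and 225 and 0 for the difference between genotypes over time (1 when the genotype labels themselves were exchanged within each day). The regrouping with 4434 genes in control was 1 of 2 others there with any gene passing. How many of its arrays kept their true day was not recorded, so what it reflects is not known.

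At day 0 in Nos3-/-, 10 of 37 fibroblast genes were lower and 9 of 29 pluripotency genes higher, with shifts of -0.65 (permutation p = 0.00749) and 0.72 (permutation p = 0.0584) in the mean over each list. Less dilution of pluripotent cell RNA by feeder RNA would raise the formative list too, but its shift was -0.43 (permutation p = 0.0283), and the pluripotency shift minus the formative shift was 1.15 (95% interval 0.05 to 2.09). That interval took in 0 in 7 of 16 omissions of 1 array, the formative shift was -0.19 without Nos3-/- replicate 5, and with the fibroblast covariate the pluripotency median went from 0.66 to 0.20, which goes with dilution, so dilution stays open. Fewer feeder cells of one composition would lower the immune list, shifted by -0.16 (permutation p = 0.613), as much as the fibroblast list, and the immune shift minus the fibroblast shift was 0.49 (95% interval -0.06 to 1.06), which leaves this open. With the fibroblast mean as a covariate 264 genes passed, against 2504 in the same day 0 arrays without it and 257 in both. This does not settle it, since errors grew too: Lhx1 went from -3.08 (SE 0.84) to -2.93 (SE 1.13), while Col1a1, a member of the list, went from -1.26 (SE 0.35) to -0.37 (SE 0.33). A smaller share of feeder fibroblasts stays open for the fibroblast genes, as do genotype and strain.

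At day 11, 12 of 29 yolk-sac and 13 of 26 Hox genes were lower and 6 of 17 formative epiblast genes higher in Nos3-/-, and camera called these lists at its preset correlation and not with estimated ones (adjusted p = 0.416, 0.294 and 0.416). That 1 array that stands apart, Nos3-/- replicate 3, made the pattern is argued against by the 7 of 7 leading lists that kept camera call and direction without it at the preset correlation, with medians such as -0.82 for yolk sac, -0.59 for Hox and 0.63 for formative epiblast genes. Those calls depend on that correlation, since camera with estimated ones called 0 of 41 lists with all arrays (4 at an unadjusted p under 0.05, and fry called 13), and without replicate 3 the lists called at the preset one were 12 in place of 17, so this array did add to the weaker lists. A uniform lag of differentiation was taken to hold back heart and yolk-sac genes by the same share of the control gain. This requires that both rise at the same time. Nos3-/- cells reached 0.97 of the control gain of the cardiac transcription factor list and 0.29 of that of the yolk-sac list, a difference of 0.67 (95% interval 0.21 to 1.12). Against the yolk-sac share, that of the contractile list was higher by 0.51 (95% interval 0.10 to 1.05), that of the second heart field list by 1.13 (0.26 to 2.85) and that of the valve list by 0.24 (-0.27 to 0.81), so the valve list leaves a lag open. These are means over each list. By medians the contractile list rose by 0.80 in control and 0.23 in Nos3-/-, which goes with a lag, and the cardiac factor mean, lower from day 0 on, still ended at 7.58 against 8.14. The interval for cardiac factors stayed above 0 in 31 of 31 omissions of 1 array. An equal share of the control gain in the yolk-sac and cardiac transcription factor lists is thus argued against. With 2 days measured, a lag of lists that rise at different times cannot be told from other causes, so a uniform lag stays open, as does a lag of part of the lists. A different mix of cell types in the embryoid bodies of the 2 genotypes or strains may be involved, which was not tested.

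Genes differing between genotypes in the same direction on both days could reflect sequence differences under the probes between strains. A second probe set followed the first for 109 of 177 such genes (61.6%) and for 120 of 177 genes changed over time by a like amount (67.8%), a shortfall of 6.21 percentage points (95% interval -3.39 to 16.4), which leaves this open, and 9 and 1 of them had a second probe set going the opposite way. Strain background in place of the loss of Nos3 cannot be told apart, since 0 of the Nos3-/- arrays are of the control strain.

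Single arrays lay far from the others of their group in 40 of 428 groups of values tested, where chance gives about 1 in 20. In Nos3-/- at day 0 replicate 3 they were Fbxo15 (8.02), Postn (10.50), Tbx20 (6.81), Tek (4.96), Fbn2 (7.26), Pou5f1 (11.55) and Fzd5 (12.64), and the list means of pluripotency (8.67), cardiac transcription factors (7.25) and oxidative stress (10.5). In Nos3-/- at day 11 replicate 3 they were Gata6 (6.32), Nnt (10.28), Aplnr (5.18), Igf2 (11.26), Prtg (9.82), Fgf5 (8.57) and Fzd5 (8.98), and the list means of definitive endoderm (7.64), Wnt (6.98), imprinted genes (7.90) and yolk sac (6.63). Other Nos3-/- values at day 0 were Col1a1 in replicate 5 (8.21), and the means of surface ectoderm (7.96) and Y-linked genes (6.90) in replicate 1 and of interferon genes in replicate 6 (8.25). In control at day 0 they were Zfp874a (4.85), Dnph1 (8.04), Lefty1 (12.75) and the formative mean (9.94) in replicate 1, the Y-linked mean in replicate 4 (5.63), Afp (6.38), Ttr (8.91), Apob (8.72) and the yolk-sac mean (8.39) in replicate 5, Isl1 in replicate 6 (6.73) and Olig2 in replicate 10 (3.50). In control at day 11 they were the Y-linked mean in replicate 3 (3.71), Wdfy1 in replicate 4 (10.39), and Pou3f1 (9.58) and Ereg (5.40) in replicate 6.

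The change over time differed between the genotypes, by the tested difference, in these named genes: Plagl1 (-4.07), Tdo2 (-3.35), Postn (-2.79), Hoxd1 (-2.34), Prdm6 (-1.95), Adamts20 (-1.94), Tek (-1.84), Phlda2 (-1.54), Hey2 (-1.47), Tmem87a (-1.15), Trim12a (-0.74), Wnt6 (0.77), Pmaip1 (0.93), Pou3f1 (1.64), Cav1 (1.76), Sema3c (1.80), Fzd5 (2.37), Ppbp (2.42), Mmp13 (2.50), Ereg (2.58), Grem1 (2.62), Lefty1 (2.81) and Fgf5 (3.05). It did so in the lists of the formative epiblast (0.89), surface ectoderm (0.77), definitive endoderm (0.69), p53 (0.34), Notch (0.20), oxidative phosphorylation (-0.14), Hox (-0.43) and yolk sac (-1.10). These 8 camera calls are those at the preset correlation, and with estimated ones 0 were called (smallest adjusted p = 0.167, 4 at an unadjusted p under 0.05), fry called 2, and definitive endoderm lost its call in 5 omissions of 1 array.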

How the results depend on the processing

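The settings that leave out 3 or 4 arrays, or use the fibroblast covariate, were chosen after seeing the data. All counts stayed within 1.5 times under quantile normalization, median centring, leaving out genes below the lower tertile of mean level, other choices of probe set and eBayes with trend and robust. With genes below the median of mean level left out, so that fewer were tested, 1121 genes passed at day 11, 3835 over time in control and 3756 over time in Nos3-/-, and 11 lists were called at day 11 and 11 over time in Nos3-/-. Array quality weights gave 3939 genes at day 11, 1590 for the difference between genotypes over time, and -0.58 for Nos3 in that difference (limma adjusted p = 0.0116). With only the arrays compared, 3679 genes passed over time in Nos3-/-, and Nos3 at day 0 was 0.33 (limma adjusted p = 0.0548). With estimated correlations 0 lists were called in each comparison, and fry called 2 for the difference over time. For these settings the cause was not tested, apart from the genes left out.

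The 3 arrays first left out were Nos3-/- day 11 replicate 3, control day 11 replicate 3 and control day 0 replicate 4, and Nos3-/- day 0 replicate 3 was added as the fourth once its list means had been seen. Without 3 arrays the counts, in the order day 0, day 11, time in control, time in Nos3-/- and difference, were 3286, 2003, 5776, 6058 and 460, with 18, 12, 19, 22 and 9 lists. Without 4 they were 4534, 2230, 5998, 6482 and 1085, with 18, 12, 19, 23 and 12 lists, and Nos3 in the difference was -0.57 (limma adjusted p = 0.0473). With the fibroblast covariate 264 genes passed at day 0, 256 of them among the 3029, and 10 lists were called. The fibroblast list itself has no value there, as the covariate fixes it.

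Direction turned in 4 results for named genes: Smad2 at day 0 (0.56) and day 11 (0.92) with the mean of its probe sets, and Ang at day 11 (-0.069) and Igfbp5 over time in Nos3-/- (-0.033) without the suffixes _x_at and _s_at, where another probe set stands for the gene. Ndufv1 did not pass at day 0 without those suffixes (0.15). Pou5f1 over time in Nos3-/- passed with array weights (-0.47) and without 4 arrays (-0.52), Ryr2 at day 11 did not without 3 arrays (adjusted p = 0.0611), nor Mmp13 in the difference (0.0666), nor Ppbp without 4 (0.0509).

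Leaving out each array in turn gave 1471 to 4142 genes at day 0, 1345 to 2295 at day 11, 5645 to 6641 over time in control, 4391 to 6092 over time in Nos3-/- and 88 to 745 for the difference. Nos3 ranged from 0.30 to 0.38, -0.21 to -0.12, 0.35 to 0.45, -0.15 to -0.07 and -0.56 to -0.46 (limma adjusted p from 0.0419 to 0.173 for the last). Lists called ranged over 17 to 20, 12 to 22, 17 to 21, 18 to 22 and 7 to 12. Of gene results, 4499 stayed, 57 lost and 1 gained a call, and of list results 6243 stayed, 46 lost and 66 gained. These gene results flatter the naming rule, since the printed genes were picked with them known. Under the other alternatives 152 of 492 genes the rule allows (30.9%) lost a call, against 24 of 146 printed (16.4%).

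The replicate numbers do not pair the arrays: correlations of arrays with 1 number ran from -0.27 to 0.35, and in no pair of groups were all above 0.1. As a block the replicate numbers gave 2118, 1423, 6084, 5587 and 165 genes and 17, 14, 19, 21 and 8 lists. Of the named genes 6 then lost their call, Col1a1 (adjusted p = 0.12), Gata6 (0.0514) and Sox17 (0.0524) at day 0, Ryr2 (0.108) at day 11, and Fgf5 (0.0802) and Mmp13 (0.0767) in the difference. So did 5 lists, Notch (0.06) and cell cycle (0.0688) at day 0 and smooth muscle (0.0603), epicardium (0.0645) and immune cells (0.258) at day 11, while 3 gained one, the BMP and TGF-beta list over time in control (0.0483) and pluripotency and germline genes over time in Nos3-/- (0.0456 for both). Comparing arrays of 2 groups alone gives no value for the difference over time, and Nos3 has none with genes below the median left out. No scaling moved the median of all genes by over 0.1. Signal over background cannot be judged from RMA values, and dim genes are the least certain.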

Other observations

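The genes and lists of this part are given as values, the Meg3, Mirg, Kdm5d, Uty and single-array Xist levels and the lists described were chosen after their values were seen, and no explanation was tested here.

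Some groups of genes moved over the 11 days in both genotypes without being described above. Hypoxia and glycolysis genes had 17 of 29 raised, 2 lowered and 10 not passing in control (20 higher and 2 lower adjusted over the list alone), with a median of 0.35 (camera adjusted p = 1.46e-05, and 0.375 with an estimated correlation). In Nos3-/- 12 of the 29 rose, 1 fell and 16 did not pass (13 higher and 1 lower over the list alone), with a median of 0.32 (camera adjusted p = 2.09e-05, and 0.372 with an estimated correlation). Interferon response genes had 10 of 27 lowered and 0 raised in control (1 higher and 12 lower over the list alone), with a median of -0.53 (camera adjusted p = 0.00109, and 0.436 with an estimated correlation). In Nos3-/- 11 of the 27 fell and 1 rose (1 higher and 11 lower over the list alone), with a median of -0.58 (camera adjusted p = 0.000896, and 0.395 with an estimated correlation). Oxidative stress genes in Nos3-/- had 12 of 25 lowered, 0 raised and 13 not passing (0 higher and 13 lower over the list alone), with a median of -0.34 (camera adjusted p = 0.000142, and 0.329 with an estimated correlation). The differences between genotypes in these changes had medians of -0.01, -0.09 and -0.12 for hypoxia, interferon and oxidative stress genes and were not called (camera adjusted p = 0.808, 0.871 and 0.627 under limma).

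At day 0, Wnt pathway genes had 8 of 35 lower in Nos3-/- and 0 higher (0 higher and 8 lower over the list alone), with a median of -0.26 (camera adjusted p = 0.000262, and 0.381 with an estimated correlation). Imprinted genes had 3 of 29 lower and 0 higher (0 higher and 3 lower over the list alone), with a median of -0.29 (camera adjusted p = 0.000908, and 0.381 with an estimated correlation). At day 11 the non-coding RNAs of the Dlk1 locus spread widely among control arrays, with Meg3 at 11.06 ± 2.37 (SD, n = 9) in control and 7.67 ± 0.69 (SD, n = 6) in Nos3-/-, and Mirg at 8.69 ± 2.11 (SD, n = 9) and 5.59 ± 0.24 (SD, n = 6). Of the 41 lists, 11 were called in no comparison, and those include the nitric oxide, skeletal muscle, neural ectoderm and retinoic acid lists. The list of Nos3 neighbours was called over time in control (median 0.04, camera adjusted p = 0.0482, and 0.369 with an estimated correlation), with 8 of 24 genes higher and 2 lower (9 and 2 over the list alone), and lost that call in 12 omissions of 1 array, with adjusted p from 0.0509 to 0.0668.

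The donors were male, per the labels. Y-linked genes averaged 7.01 ± 0.54 (SD, n = 10) and 7.40 ± 0.26 (SD, n = 6) at day 0 in control and Nos3-/-, and 6.86 ± 1.21 (SD, n = 9) and 7.18 ± 0.37 (SD, n = 6) at day 11. The lowest level of Eif2s3y, a Y-linked gene, was 7.75 among control arrays at day 0, on replicate 4, and 3.21 among those at day 11, on replicate 3. Other Y-linked genes were also low on control day 0 replicates 4 (Kdm5d 5.01, Uty 5.71) and 9 (5.31 and 6.94), against 6.90 to 8.20 and 7.47 to 8.36 on the other 8 control arrays of that day. Eif2s3y on replicate 9 was at 10.46, among the 10.19 to 10.85 of those 8, so the Y-linked genes disagree on that array. Xist, the RNA that silences an X chromosome, was at 9.38 ± 0.62 (SD, n = 10) and 8.93 ± 1.25 (SD, n = 6) at day 0 and at 7.35 ± 0.99 (SD, n = 9) and 7.30 ± 0.74 (SD, n = 6) at day 11, in control and Nos3-/-. On control day 11 replicate 3 Kdm5d and Uty were at 2.79 and 2.95, and Xist was at 9.62 against 6.65 to 8.37 on the other 8 control arrays of that day, which is the pattern of female cells. The genes that separate the genotypes put this array with control. Whether it comes from another line or carries a wrong label was not tested and stays open. The sex of the feeder cells is not given.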
